A study of Homo sapiens with 36 samples.

How the data were processed

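The measurements were ChIP-seq of H3K4me3, H2Bub, H3K27ac, H4ac, p65 and IRF1 in human monocyte-derived macrophages. Samples were assigned to antibody and condition from their titles, giving 28 groups, of which 8 held 2 samples and 20 held 1. The deposited files were 28 peak lists, 1 for each group, with chromosome, start, end and a peak name. The header lines name columns of a peak caller's output, among them a score, tag counts and fold changes, but every deposited list had 0 rows with a value in these columns. Whether the 2 samples of a group were pooled before calling is not given in the sources used here. The submitters' processing notes name FastQC, BWA and the build hg19, without versions. Per the file headers, tags were normalized to the control in the H2Bub, p65, H3K27ac N and H3K27ac TL lists, the control was normalized to the tags in the H3K4me3, H4ac, H3K27ac L and H3K27ac T lists, and no control was named for IRF1. Read depth, peak height and enrichment are therefore unknown, and the number of peaks in a list also moves with depth and with the calling.

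Lists were compared on chromosomes 1 to 22 and X. The covered lengths in Mb were computed from the peak positions. A peak counted as shared when at least 1 bp was overlapped by a peak of the other list, and as gained or lost otherwise. No test was applied to a pair of lists. For each comparison the 3 longest gained and the 3 longest lost peaks were eligible to be named, and for p65 and IRF1, whose peaks have a fixed or nearly fixed length, the first 3 in file order. The report names some of these where lists of the same kind repeat. Coordinates are given in hg19, counted from 1. Shares of gained and lost peaks with a p65 T or IRF1 IFN_T peak carry Wilson 95% intervals, and differences of shares carry 95% normal intervals. These shares were added after seeing the data. The overlap of p65 and IRF1 peaks was set beside 100 random placements inside the union of the H3K27ac, H3K4me3 and H4ac lists.

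For H3K4me3 and H2Bub, the percent of each 1 kb bin covered by peaks was computed in each of the 8 lists. limma 3.58.1 in R 4.3.3 fitted TNF, IFNA and LPS as additive terms with empirical Bayes moderation and a variance trend, with 4 residual degrees of freedom. Bins with a mean cover under 5 percent or identical in all 8 lists were left out, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The residuals hold both the interactions and the noise, and p-values measure only the spread between these lists. Neighbouring bins are not independent. For named bins, the 10 with the largest change in each direction were taken, with ties in chromosome order. Exact sign-flip permutation tests over the 4 pairs of lists that differ in 1 treatment cannot give a two-sided p under 0.125.

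The overlap operations were tested on simulated data and gave 0 wrong answers in 50 trials of 40 peaks. In simulated H3K4me3 lists of 68785 bins with 200 bins changed by TNF, 100 by 90 points and 100 by 50 points, the model recovered 100% of the larger and 0% of the smaller changes, and 6.54% of its calls were false. Without the trend it recovered 100% of both sizes, and 20.6% of its calls were false. In simulated H2Bub lists of 384392 bins it recovered 0% of 200 changed bins at either size, and 100% when 20000 bins changed. The simulated lists were made by shuffling the values of each bin over the lists, each bin on its own. That removes structure shared between bins, so these rates need not hold for the real lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

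Alternatives fixed before the data were examined were an overlap of at least 50 percent of the peak, the longest 75 percent of each list, equal list lengths by keeping the longest peaks, merging of peaks within 1 kb, chromosomes 1 to 22 alone, and for the model quantile normalization, no filter, no trend, a TNF by IFNA term and each list left out in turn. With equal list lengths, gained and lost counts can differ only where a peak of 1 list overlaps several of the other, so their balance was not read as a direction of change. Counts of regions by set of lists were recomputed with the longest 75 percent, with merged peaks and on chromosomes 1 to 22. The reference used here gives gene positions on GRCh38.p14 and not on hg19, and coordinates were not converted. The planned assignment of peaks to genes, the 10 gene lists, their camera test and the search for 6 motifs were therefore not run, and the model was fitted on bins instead of genes.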

Results

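Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in human macrophages grown from CD14-positive blood monocytes with M-CSF. The 36 samples covered 6 antibodies. H3K4me3 marks promoters, H3K27ac and acetylated H4 (H4ac) mark active promoters and enhancers, and monoubiquitinated H2B (H2Bub) lies over transcribed gene bodies. p65 is the transactivating subunit of NF-κB, and IRF1 is a transcription factor of the interferon response. Cells were left untreated (N) or received TNF (T, 10 ng/ml for 24 h), IFNA (IFN, 25 ng/ml for 24 h), LPS (L, 10 ng/ml for 3 h) or their combinations (TL, IFN_L, IFN_T, IFN_TL). Each of the 28 combinations of antibody and condition had 1 peak list. H3K4me3 and H2Bub were measured in all 8 conditions, with 2 samples in each of the conditions N, L, T and TL and 1 in each condition with IFNA. H3K27ac and H4ac were measured in N, L, T and TL, p65 in N and T, and IRF1 in N and IFN_T, with 1 sample each. The lists carried positions in hg19 and no score, height or read depth, so the depth behind each peak is unknown. There was no replicate spread for any comparison of a pair of lists. In what follows a peak is called gained when it was in the first list and not overlapped by any peak of the second, and lost in the opposite case. The balance of gained and lost counts largely follows the lengths of the lists compared and gives no direction of change by itself.

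On chromosomes 1 to 22 and X, the H3K4me3 lists held between 20411 (T) and 24917 (L) peaks and covered between 28.2 Mb (T) and 37.7 Mb (IFN_TL). The H2Bub lists held between 65393 (IFN_TL) and 86538 (IFN) peaks over 218 to 256 Mb. The H3K27ac lists held 69818 peaks in N, 67919 in L, 55753 in T and 64626 in TL. H4ac gave 18532 peaks in N, 16789 in T, 12265 in L and 11422 in TL. The p65 list grew from 23889 peaks in N to 40717 in T, and the IRF1 list from 5038 in N to 12368 in IFN_T.

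The first question was which factor sites appeared with TNF. Nearly all p65 peaks of TNF-treated macrophages were absent from the untreated list: 38450 were gained, 2267 were shared and 21622 peaks of the untreated list were lost. The gained sites lay in acetylated chromatin. Of the gained sites, 68.9% overlapped an H3K27ac peak of the T list and 67.3% already overlapped one of the N list. Of the shared sites, 69.9% lay on an H3K4me3 region of any list, against 29.9% of the gained sites and 2.35% of the lost sites. Among the lost sites, 4.35% overlapped an H3K27ac peak of the N list, and 92.6% lay outside every H3K4me3 and H3K27ac region. All p65 peaks had the same length, so the named peaks were taken in the order of the file: the first gained peaks were at chromosome 10, 42398510 to 42398810 and 42400241 to 42400541, and chromosome 1, 144989475 to 144989775. The first lost peaks were at chromosome 22, 16861539 to 16861839, chromosome 6, 58778953 to 58779253, and chromosome 21, 9827202 to 9827502. The first peaks in file order, for p65 and for IRF1 alike, include positions beside centromeres that may be repeats, and no list of regions to exclude was used.

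The IRF1 list also grew, with IFNA and TNF together. Of the IRF1 peaks in IFN_T, 10111 were gained over N and 2257 were shared, while 2781 peaks of N were lost. In contrast to p65, IRF1 sites overlapped H3K27ac of the T list to similar extents in all classes, at 36.3% of gained, 37.1% of shared and 35.1% of lost sites. H4ac of the N list differed more between the classes, at 15.8% of gained, 23.2% of shared and 21.7% of lost sites. The first gained peaks in file order were at chromosome 16, 46403564 to 46403832, chromosome 8, 70602298 to 70602566, and chromosome X, 108297609 to 108297877. The first lost peaks were at chromosome 21, 9825410 to 9825704, chromosome 16, 33963782 to 33964076, and chromosome 3, 75698247 to 75698541.

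Peaks of p65 and IRF1 were also compared with each other. The stimulated lists come from different treatments, TNF for p65 and IFNA with TNF for IRF1. Of the 40717 p65 peaks in T, 3063 (7.52%, Wilson 95% interval 7.27 to 7.78) overlapped an IRF1 peak of IFN_T. Within chromatin marked by H3K27ac, H3K4me3 or H4ac, 2737 of 31866 p65 peaks did so, against a mean of 441 and a highest value of 490 over 100 random placements in the same chromatin, a ratio of 6.21. When the centre of the p65 peak had to lie inside the IRF1 peak the share was 6.18%. For the p65 T list and the IRF1 list of untreated cells the ratio was 6.12. The untreated p65 list, with 3197 peaks inside this chromatin, gave higher ratios, of 9.01 with IRF1 of IFN_T (407 peaks) and 20.1 with IRF1 of N (386 peaks). The placements were uniform within the marked regions, so the ratios do not account for any shared preference of the factors within them. Nor do they account for repeats that may be called in both lists. No list of regions to exclude was used, and no control was named for IRF1. Read from the IRF1 side, 24.1% of gained IRF1 peaks (23.3 to 24.9) carried a p65 peak of T, and 6.01% carried one of N. Intervals here and below cover counting error over peaks only, and neighbouring peaks are not independent.

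Sites where gained p65 and gained IRF1 peaks coincided were acetylated more often than gained sites of either factor alone, and H4ac covered more of them with TNF. Of 2230 such sites, 76.1% overlapped H3K27ac in N and 83.5% in T, 77.7% in L and 82.1% in TL. H4ac covered 38.2% of them in N, 50.8% in T, 33.9% in L and 36.7% in TL. At gained p65 sites without IRF1, H4ac covered 28.7% in N and 31.5% in T, then 20.03% in L and 18.5% in TL. Gained IRF1 sites without p65 overlapped H3K27ac at 22.3% in N and 22.1% in T. No H3K27ac or H4ac list with IFNA was analysed here, so acetylation at IRF1 sites of IFN_T was read only in other conditions. In windows of the same length as a p65 peak, at the centres of H3K27ac regions without either factor, H3K27ac was present at 52.9% in N, 27.5% in T, 42.3% in L and 41.1% in TL. These regions were chosen to lack p65 peaks of T, which by itself lowers the share in the T list. These differences between single lists were not tested.

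**Figure D1:**
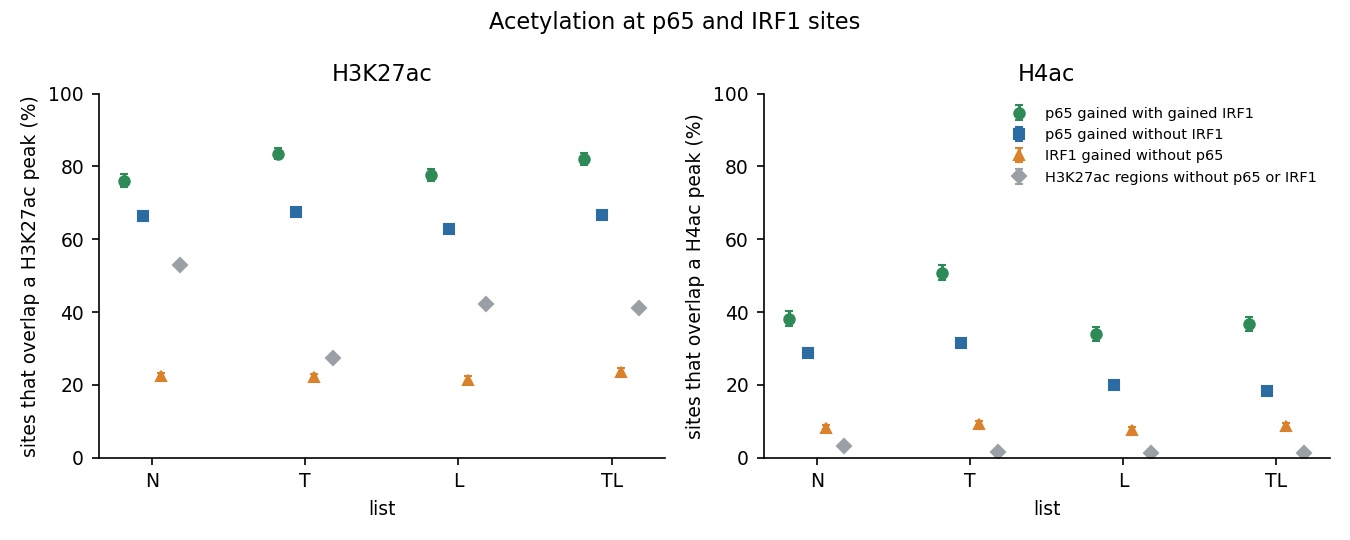
Share of sites (%) that overlap an H3K27ac or H4ac peak in the N, T, L and TL lists, for 4 classes of sites, with Wilson 95% intervals. At sites with gained p65 and gained IRF1, H4ac coverage went from 38.2% in N to 50.8% in T and was 36.7% in TL.

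For TNF alone against untreated cells, H4ac, H3K27ac and H3K4me3 peaks that were gained carried p65 more often than those that were lost. The shares with p65 or IRF1, here and in the comparisons that follow, were added after seeing the data. A p65 T peak lay in 69.2% of gained and 42.2% of lost H4ac peaks, a difference of 27.05 points (95% interval 25.3 to 28.8). For H3K27ac the shares were 20.1% and 7.16%, a difference of 12.9 points (12.2 to 13.7), and for H3K4me3 24.0% and 13.1%, a difference of 10.9 points (9.24 to 12.6). For H2Bub they were 5.45% and 4.44%, a difference of 1.005 points (0.628 to 1.38). Peaks shared by both lists held p65 more often than the gained ones, at 71.9% for H4ac, 47.1% for H3K27ac, 40.5% for H3K4me3 and 11.5% for H2Bub. IRF1 peaks of IFN_T also lay more often in gained than in lost H4ac peaks, at 14.1% and 4.95%. The numbers were 4846 gained and 6583 lost peaks for H4ac, 12909 and 29942 for H3K27ac, 3505 and 5793 for H3K4me3, and 24583 and 26452 for H2Bub. Among regions gained in H4ac and H3K27ac, 495 of 646 (76.6%) held a p65 peak, and among the 54 gained in H4ac, H3K27ac and H3K4me3 together 46 did. The longest gained H3K27ac peaks lay at chromosome 10, 92751984 to 92771063 (19.1 kb), chromosome 1, 201359729 to 201377099 (17.4 kb), and chromosome 3, 99234022 to 99249523 (15.5 kb), and all of them held a p65 T peak. None of the 3 longest lost H3K27ac peaks did, at chromosome 10, 105533862 to 105555410, chromosome 11, 128803131 to 128819067, and chromosome 1, 159398311 to 159413516. The longest gained H4ac peak covered chromosome 11, 35363622 to 35390163 (26.5 kb). All of the 3 longest gained H4ac peaks held a p65 peak, and so did 2 of the 3 longest lost ones. The longest gained H3K4me3 peak, at chromosome 2, 143641014 to 143652410 (11.4 kb), held none, while those at chromosome 16, 56699502 to 56706612 (7.11 kb), and chromosome 5, 35856802 to 35862741 (5.94 kb), did. None of the 3 longest lost H3K4me3 peaks held one. With the longest 75 percent of each list the difference in p65 was 21.6 points for H3K4me3 and 20.8 for H3K27ac, and in windows of equal length at the peak centres it was 0.308 points for H2Bub. The H3K27ac lists N and T also differed in whether the tags or the control had been rescaled, per the file headers.

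With LPS alone, the difference in p65 between gained and lost peaks of H4ac, H3K27ac and H3K4me3 lay on either side of 0 depending on the setting. In the lists as deposited, the shares with a p65 T peak were 52.1% of gained and 53.1% of lost H4ac peaks, 10.6% and 10.2% for H3K27ac, and 15.5% and 15.5% for H3K4me3, each with overlapping intervals. They were 6.26% and 5.30% for H2Bub, a difference of 0.955 points (0.549 to 1.36), which was -0.426 points (-0.860 to 0.00759) with equal list lengths. The H4ac difference was -10.5 points (-12.3 to -8.77) with equal list lengths, -5.88 points (-7.54 to -4.22) in windows of equal length at the peak centres and 2.19 points (0.301 to 4.07) with the longest 75 percent. The H3K27ac difference was -3.16 points (-3.73 to -2.60) when 50 percent of the peak had to be overlapped and 1.56 points (0.790 to 2.32) with the longest 75 percent. For H3K4me3 these settings gave 2.23 points (0.738 to 3.73) and -4.00 points (-6.67 to -1.32). IRF1 lay in 12.1% of gained and 7.46% of lost H4ac peaks. The gained and lost counts were 4413 and 10640 for H4ac, 24792 and 30548 for H3K27ac, 5790 and 3301 for H3K4me3 and 20355 and 35802 for H2Bub. The longest gained H3K4me3 peaks lay at chromosome 4, 185769161 to 185776858 (7.70 kb), chromosome 9, 123682066 to 123689541 (7.48 kb), and chromosome 2, 113537208 to 113542759 (5.55 kb), and each held a p65 peak of the T list, as did 2 of the 3 longest lost ones. The longest gained H4ac peak, at chromosome 12, 24848619 to 24886237, spanned 37.6 kb.

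Cells given LPS after TNF were compared with cells given LPS alone and with cells given TNF alone. Against LPS alone, TL gained 5360 and lost 6993 H3K4me3 peaks, of which 24.1% and 10.7% held a p65 T peak. H3K27ac gained 20815 and lost 21874 peaks, of which 11.7% and 7.64% did. For H4ac, 2621 peaks were gained and 3698 lost, with p65 in 49.5% and 46.0%, and with IRF1 in 15.1% and 6.17%. The H4ac difference in p65 turned negative, at -0.416 points, when 50 percent of the peak had to be overlapped, and at -2.38 points with the longest 75 percent of each list, and it was 0.0727 points with equal list lengths and 0.763 points with peaks within 1 kb merged. In windows of equal length at the peak centres it was 4.96 points (2.58 to 7.33). H2Bub gained 27801 and lost 18957 peaks. The longest H3K4me3 peaks gained were at chromosome 16, 56665323 to 56673088 (7.77 kb) and 56699229 to 56706155 (6.93 kb), and chromosome 1, 209860069 to 209865274 (5.21 kb). The 3 longest gained H3K4me3 peaks held p65 and the 3 longest lost ones did not. The longest H4ac peak lost lay at chromosome 4, 74583849 to 74602867 (19.0 kb). A p65 peak lay in 2 of the 3 longest lost and in all of the 3 longest gained H4ac peaks.

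Against TNF alone, p65 was less frequent in gained than in lost acetylation peaks. H4ac gained 1884 and lost 7493 peaks in TL, and a p65 T peak lay in 32.9% of the gained and 64.6% of the lost ones, a difference of -31.7 points (-34.1 to -29.3). For H3K27ac, with 23578 gained and 14370 lost, the shares were 8.39% and 15.3%. H3K4me3 gained 6444 and lost 3212 peaks, with shares of 19.3% and 11.99%. H2Bub gained 18643 and lost 24142 peaks.

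Because every planned H3K27ac comparison set lists with different headers side by side, lists with the same header were compared as well, a choice made after seeing the data. T against L gave 16260 gained and 26928 lost peaks, with p65 in 17.0% and 6.70%, and TL against N gave 22697 and 29906 with 13.8% and 9.56%.

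**Figure D2:**
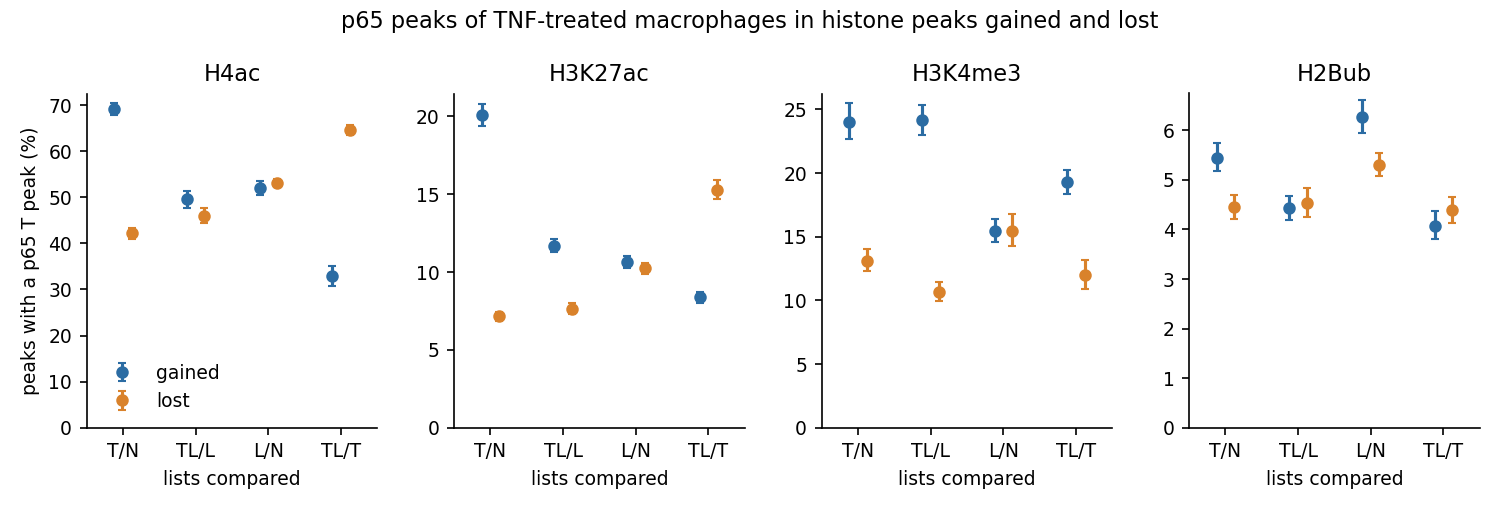
Share (%) of gained and of lost peaks that hold a p65 peak of the T list, for 4 histone marks and 4 comparisons, with Wilson 95% intervals and a separate vertical scale per mark. In T against N the gained peaks lie above the lost ones for H4ac (69.2% and 42.2%), H3K27ac and H3K4me3, while in L against N the intervals of gained and lost peaks overlap for these 3 marks in the lists as deposited.

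The series title names cooperation of type I interferon and TNF, and the lists with IFNA address it for H3K4me3 and H2Bub. IFNA alone gained 5104 and lost 5604 H3K4me3 peaks over N, and p65 T peaks lay in 11.8% and 11.9% of them. On top of TNF it gained 6154 and lost 3034 peaks, with p65 in 21.3% and 16.6%, and on top of TNF and LPS 4916 and 5093, with p65 in 22.8% and 16.9%. On top of LPS it gained 3029 and lost 7472, with p65 in 17.6% and 11.5%. The longest H3K4me3 peak gained with IFNA, at chromosome 2, 218926335 to 218934114 (7.78 kb), lay where the longest one gained on top of TNF did, at 218927903 to 218935112 (7.21 kb), and neither held p65 or IRF1. Another gained on top of TNF, at chromosome 1, 192544836 to 192550059 (5.22 kb), held both p65 and IRF1. IFN_TL against IFN_L gained 5652 and lost 3076 peaks, with p65 in 26.9% and 12.5%, and against IFN_T it gained 3324 and lost 3412, with p65 in 25.1% and 15.2%. IFN_T against IFN, added after seeing the data, gained 6175 and lost 4902, with p65 in 23.8% and 9.79%. With the longest 75 percent of each list, the p65 difference for IFNA alone was 5.62 points (3.27 to 7.96). On top of LPS it was 18.04 points (15.1 to 20.9), against 6.05 as deposited. In windows of equal length at the peak centres it was 2.65 points on top of TNF, against 4.69 as deposited. On top of TNF and LPS it was 3.14 points there, against 5.94.

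H2Bub behaved differently. In each of the 4 comparisons that added IFNA, p65 sites were less frequent in gained than in lost H2Bub peaks: 2.79% and 5.50% over N, 2.79% and 5.71% over L, 2.54% and 5.72% over T, and 2.98% and 5.54% over TL. The gained and lost counts were 27492 and 27932 over N, 25188 and 19549 over L, 19241 and 28149 over T, and 19908 and 25933 over TL. IFN_TL gained 16942 and lost 19933 peaks against IFN_L, and 18283 and 21381 against IFN_T. IFN_T against IFN, added after seeing the data, gained 19446 and lost 29510. The longest H2Bub region gained with IFNA on top of TNF ran over 102 kb at chromosome 9, 116674009 to 116775573, and it overlapped 2 of the 3 longest gained with IFNA alone, at 116722161 to 116750011 and 116674000 to 116700430. TNF alone gained 108 kb at chromosome 8, 18763348 to 18871109, and lost 104 kb at chromosome 14, 52327748 to 52432243. The lists with IFNA came from 1 sample each and the others from groups of 2, so sample number and IFNA went together here.

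The 8 H3K4me3 lists form a full layout of the 3 treatments, which limma fitted on the percent of each 1 kb bin covered by peaks. With TNF, 588 bins were more covered and 206 less covered among 68785 tested (Benjamini-Hochberg adjusted p under 0.05). The more covered bins held a p65 T peak in 27.6% of cases (24.1 to 31.3), against 18.7% of all tested bins and 11.7% (7.96 to 16.7) of the less covered bins. The bins with the largest change went from no cover in the 4 lists without TNF to full cover in the 4 with it, a change of 100 points (SE 6.40, adjusted p = 0.00242). Many bins tied at that value, so the 10 named were taken in chromosome order, all on chromosome 1: 1148001 to 1149000, 159798001 to 159800000, 201367001 to 201369000, 207998001 to 207999000, 209861001 to 209864000 and 221909001 to 221910000. The longest run of more covered bins was chromosome 16, 56700001 to 56706000. The 10 bins with the opposite change were at chromosome 2, 169926001 to 169928000, chromosome 3, 50376001 to 50377000, 52530001 to 52532000 and 112692001 to 112694000, chromosome 4, 47913001 to 47915000, and chromosome 5, 42808001 to 42809000. A change of 100 points in these bins means that all 4 pairs of lists that differ in TNF alone share the direction. Such bins leave no residual spread in the fit. Their SE and adjusted p therefore rest on the moderation over all bins. The number of called bins was between 244 and 510 without any 1 of the 8 lists, and 520 with no filter.

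With IFNA, 101 bins were more covered and 4 less. limma gave 3911 bins at an unadjusted p under 0.05, where chance gives 3439. The lists with IFNA came from 1 sample each and the others from groups of 2. The IFNA term can therefore not be told apart from sample number. An IRF1 peak of IFN_T lay in 8.91% of the more covered bins (4.76 to 16.1), against 4.30% of all tested bins, and a p65 peak in 9.90%. The 10 named bins were at chromosome 1, 79091001 to 79093000, 79120001 to 79121000 and 226044001 to 226045000, and chromosome 2, 7001001 to 7003000, 7022001 to 7023000, 191873001 to 191874000, 218928001 to 218929000 and 218931001 to 218932000, each with a change of 100 points (SE 6.40, adjusted p = 0.0068). As with TNF, the SE and adjusted p of these bins rest on the moderation over all bins. Runs of 5 bins lay at chromosome 3, 172231001 to 172236000, chromosome 2, 218928001 to 218933000, and chromosome 10, 91156001 to 91161000. The 4 less covered bins were at chromosome 4, 11428001 to 11429000, chromosome 1, 28834001 to 28835000, chromosome 14, 59216001 to 59217000, and chromosome 9, 127998001 to 127999000. limma called 0 bins after leaving out N, T, IFN_L, IFN_T or IFN_TL, and 65 after leaving out TL.

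LPS gave 13 more covered bins and no less covered ones, with 2668 bins at an unadjusted p under 0.05 where 3439 are given by chance. The 10 named were at chromosome 2, 64366001 to 64368000, chromosome 7, 30516001 to 30517000 and 38295001 to 38296000, chromosome 12, 123200001 to 123201000, chromosome 18, 57569001 to 57570000, chromosome X, 108973001 to 108974000, chromosome 3, 73049001 to 73050000, chromosome 1, 161478001 to 161479000, and chromosome 14, 75992001 to 75993000. Their changes were between 98.8 and 100 points. No bin was called when any 1 list was left out or after quantile normalization.

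For H2Bub the same model called 0 of 384392 bins for TNF, for IFNA and for LPS. limma gave 22355, 30180 and 33602 bins at an unadjusted p under 0.05, where chance gives 19220, and without the variance trend it called 669, 1313 and 2254. In simulated H2Bub lists with 200 bins changed by TNF, 0% were recovered even at a change of 90 points, so a count of 0 for TNF does not show absence of change.

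Regions were also counted by the lists that held them, a description chosen after seeing the data. Of 41830 merged regions, 13656 were in all 8 lists. Exactly the 4 lists with TNF held 191 regions, the highest number of the 70 sets of 4 lists, whose median was 13, and 70.7% of them (63.9 to 76.7) carried a p65 T peak. The longest were at chromosome 16, 56699229 to 56706612 (7.38 kb), chromosome 1, 209858990 to 209865274 (6.29 kb), and chromosome 4, 103320221 to 103325798 (5.58 kb), all with p65. The number was 159 with the longest 75 percent of each list and 176 with peaks within 1 kb merged. As deposited, the set ranked next, N, L, IFN_T and IFN_TL, is not defined by a treatment and held 141 regions. Of the regions in all 8 lists, 50.5% carried a p65 T peak. Exactly the 4 lists without TNF held 70 regions, of which 34.3% (24.2 to 46.0) carried p65, the longest, without p65, at chromosome 5, 42805847 to 42812646 (6.80 kb). Exactly the 4 lists with IFNA held 71 regions, of which 25.4% (16.7 to 36.6) carried IRF1 and as many carried p65. Among the 3 longest, those at chromosome 2, 113855266 to 113859301, and chromosome 10, 91019865 to 91023519, carried IRF1 and that at chromosome 6, 83796289 to 83800278, did not. Exactly the 4 lists with LPS held 19, and 11 with the longest 75 percent. The lists IFN_T and IFN_TL alone shared 572 regions, the highest number of the 28 pairs of lists, whose median was 94, and 34.3% (30.5 to 38.2) carried p65. The pair ranked next, N and L, shared 551. For H2Bub the 4 lists without IFNA held the most regions of any set of 4, at 651, and the 4 lists with TNF ranked 15 with 178, or 113 with peaks within 1 kb merged. The lists with IFNA came from 1 sample each and the others from groups of 2. Counts of the sets with or without IFNA can therefore not be told apart from sample number.

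**Figure D3:**
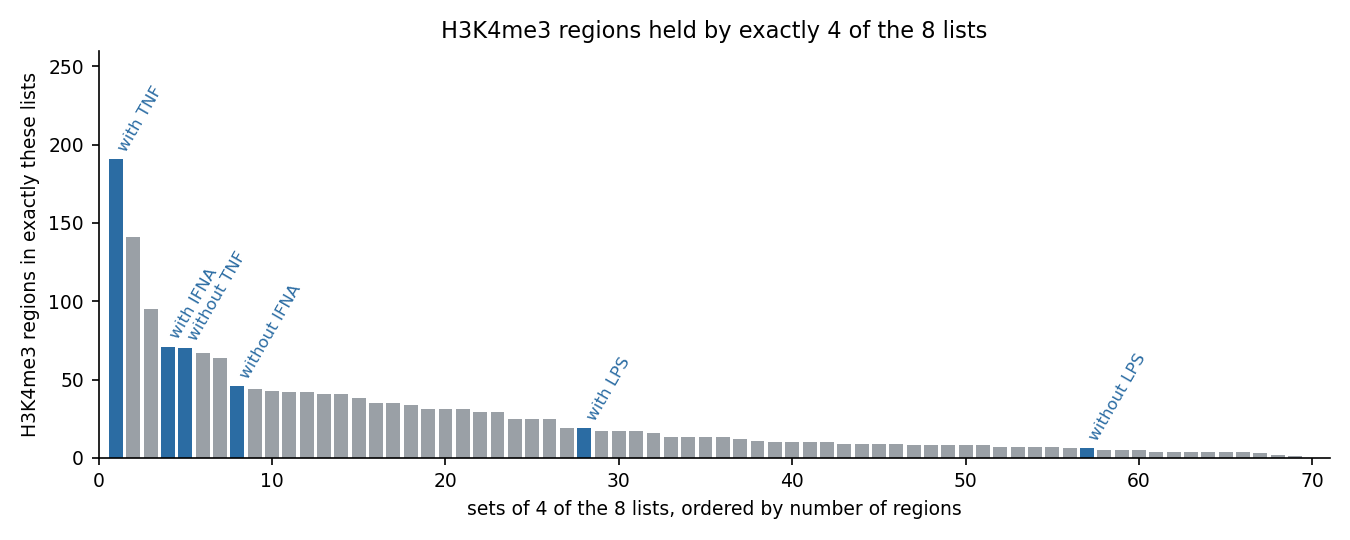
Number of H3K4me3 regions held by exactly the 4 lists of each of the 70 sets, in descending order, with the 6 sets defined by a treatment in blue. The set of all lists with TNF stands first with 191 regions and the set with LPS has 19.

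A further question was whether regions gained with LPS were also present in the lists with both TNF and LPS, with or without IFNA. Of 5790 LPS-gained H3K4me3 regions, 26.7% were in TL and 33.0% in IFN_TL. There were 473 in TL and not in IFN_TL, and 836 in IFN_TL and not in TL. The regions lost with LPS, measured the same way, leaned in the same direction with 268 and 412. Of 20355 LPS-gained H2Bub regions, 51.8% were in TL and 45.8% in IFN_TL, with 4009 in TL and not in IFN_TL against 2789 in the opposite class. Regions lost with LPS gave 6252 and 4135.

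H3K4me3 peaks covered the greatest length in the lists that combined TNF and IFNA. The covered length was 35.8 Mb in IFN_T and 37.7 Mb in IFN_TL, against 28.2 to 34.6 Mb in the other 6 lists. In the 13656 regions present in all 8 lists, the mean covered length per region was 1808 bp in N, 1778 bp in T, 1797 bp in IFN and 2085 bp in IFN_T. With LPS it was 1984 bp in L, 1992 bp in TL, 1847 bp in IFN_L and 2151 bp in IFN_TL.

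**Figure D4:**
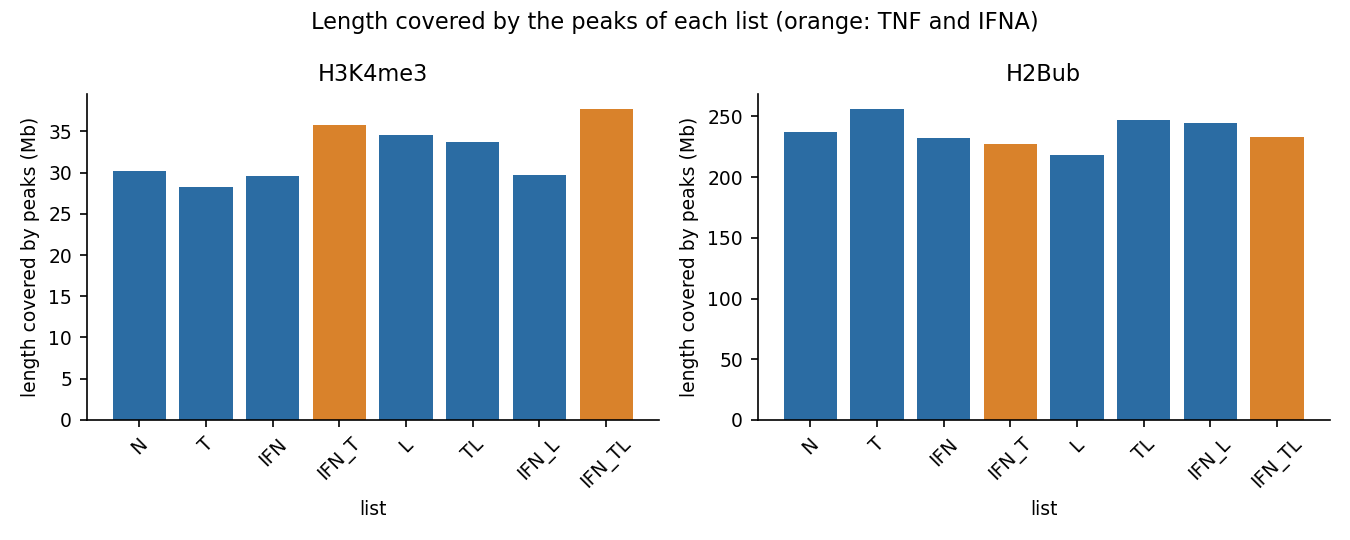
Length (Mb) covered by the peaks of each of the 8 H3K4me3 and 8 H2Bub lists, with the lists that combine TNF and IFNA in orange. For H3K4me3 those stand at 35.8 and 37.7 Mb, above all other lists, and for H2Bub they lie inside the range of the others.

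**Figure D5:**
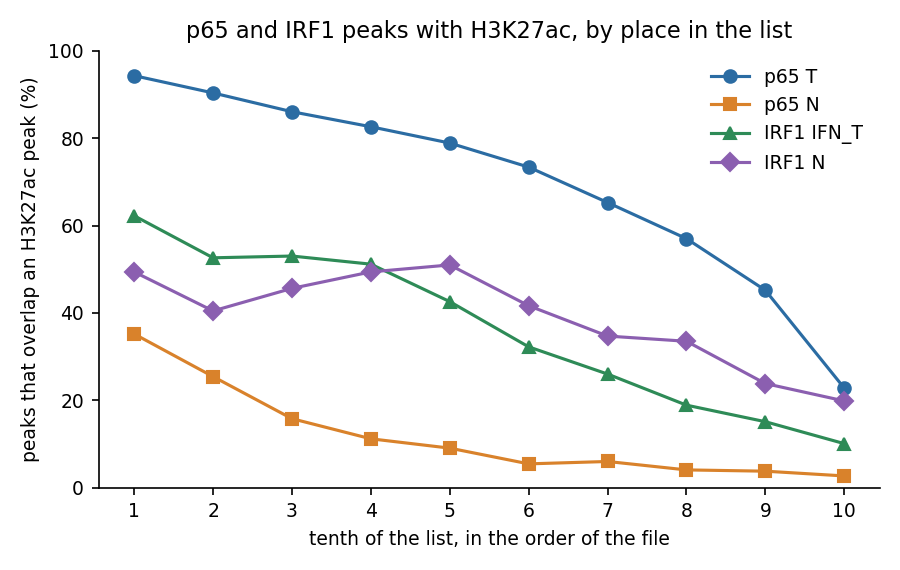
Share (%) of p65 and IRF1 peaks that overlap an H3K27ac peak, in steps of 10 percent of the list in the order of the file, using H3K27ac of N for the N lists and of T for the others. In the p65 T list it goes from 94.3% to 22.8%, and in the p65 N list from 35.2% to 2.72%.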

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

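The tests of the number of samples, of list-wide calling and of p65 background, and the quantile normalization of the TNF by IFNA term, were chosen after the result was seen. The contrasts named here compare the effect of 1 treatment in lists with and without another. In each, both pairs of lists moved one way with the other treatment and both moved the opposite way without it. Of 48 contrasts scanned, 12 did so, where independent signs give 12.5%. The contrasts are not independent, since each pair of treatments was scanned in both orders over the same lists and the measures are related. The 12.5% is therefore no chance rate for this count. Apart from the TNF by IFNA term of the model the differences were not tested.

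For H3K4me3, the covered length moved by 7.09 Mb with TNF in the presence of IFNA and by -1.44 Mb in its absence, and with IFNA it moved by 5.79 Mb with TNF and by -2.74 Mb without. The number of peaks moved by 1424 with TNF in the presence of IFNA and by -1930.5 in its absence. LPS moved it by -964 with IFNA and by 2575.5 without. The share of gained p65 sites on H3K4me3 moved by 2.46 points with IFNA in the presence of TNF and by -0.538 points in its absence.

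For H2Bub, the covered length moved by -8.15 Mb with TNF in the presence of IFNA and by 23.8 Mb in its absence, and by 8.78 Mb with LPS in the presence of IFNA and by -14.2 Mb in its absence. The number of peaks moved by -4896.5 with IFNA in the presence of TNF and by 1200.5 in its absence. The share of gained p65 sites on H2Bub moved by -0.429 points with TNF in the presence of IFNA and by 1.957 points in its absence, and by 0.801 points with LPS in the presence of IFNA and by -1.63 points in its absence. The share of gained IRF1 sites on H2Bub moved by -0.470 points with TNF in the presence of IFNA and by 1.42 points in its absence. With LPS it moved by 0.282 points in the presence of IFNA and by -1.59 points in its absence.

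In the H3K4me3 model with a TNF by IFNA term, limma called 894 bins for that term, 796 of them more covered with both treatments than the separate effects give. After quantile normalization of the lists it called 0, with 8369 bins at an unadjusted p under 0.05 and a lowest adjusted p of 0.0516. Of the 796 bins, 15.2% held a p65 peak, against 18.7% of all tested bins.

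The first pattern weighed is the greater length covered by H3K4me3 with TNF and IFNA together. All 4 lists with IFNA are of 1 sample each. IFN and IFN_L covered 29.6 and 29.8 Mb, and IFN_T and IFN_TL 35.8 and 37.7 Mb. A shift from sample number that is equal in all of these lists would not set IFN_T and IFN_TL apart from IFN and IFN_L. Whether there is such a shift cannot be read from these values, because they are the pattern itself. A greater scatter of lists of 1 sample stays open. IFN and IFN_L differed from N and L by -2.74 Mb on average, but that value is part of the pattern and no separate test of it. At regions present in all 8 lists, the TNF effect with IFNA exceeded that without by 13.3% of the breadth where a p65 or IRF1 peak lay (12.6 to 14.1), and by 20.4% where none did (19.5 to 21.4). The ratio of 0.654 runs against widening confined to p65 sites of T and IRF1 sites of IFN_T. The regions with a peak were broader to begin with, and the changes in bp were close, at 309 and 304. No p65 list with IFNA was analysed, so regions without either peak may hold p65 in IFN_T or IFN_TL. Widening confined to such sites stays open. The 20.4% at regions without these peaks is consistent with a list-wide difference in calling, and a genome-wide effect of both cytokines stays open, as untested.

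The second pattern is the untreated p65 list, of which most peaks lie outside acetylated regions. Peaks in N and not in T overlapped H3K27ac of N in 4.35% of cases, where the length of the H3K27ac peaks gives 5.94% for random positions over the 3034.6 Mb spanned by the lists, a ratio of 0.733. Peaks shared with T were left out, and 83.8% of the shared sites overlapped H3K27ac of N, which by itself lowers the share. In the whole N list the share was 35.2% in the first 10 percent of peaks in file order and 2.72% in the last. Weak or background calls are therefore a possible reading of the peaks in N alone, and the ratio does not decide for the whole list. Whether the same background is in every p65 list was not decided: the share of the T list on H3K27ac of T was 94.3% in the first 10 percent of peaks and 22.8% in the last, where background would be expected. What stays open is whether some of the 21622 peaks are binding in chromatin without acetylation.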

How the results depend on the processing

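No paired analysis was possible because the replicate numbers of the samples are carried by no value, each group having 1 peak list. The pairs of lists that differ in 1 treatment pair conditions, not replicates. The alternatives for motif windows, promoter windows, the 40 point change of H2Bub, the estimated correlation of camera and the replicate block were not run, for want of a gene annotation of hg19 or of values per replicate. Depth is unknown and no result could be weighed by it. Chromosomes 1 to 22 alone and a 50 percent overlap left all 68 counts of gained or lost peaks within 1.5 times the values as deposited. For the values that moved further, the cause was not tested, except that a shorter list holds fewer peaks by construction.

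With the longest 75 percent of each list, 31 of 64 counts moved. For H3K4me3 the gained and lost counts became 1549 and 3266 for T against N, 3108 and 1264 for L against N, 2287 and 3512 for TL against L, 3314 and 917 for TL against T, 2016 and 2409 for IFN against N, 1107 and 4434 for IFN_L against L, 3760 and 1448 for IFN_T against T, 2790 and 2918 for IFN_TL against TL, 3647 and 1750 for IFN_TL against IFN_L, and 1841 and 1916 for IFN_TL against IFN_T. For H3K27ac they became 12729 and 13349 for TL against L and 15278 and 8583 for TL against T, and the gained counts 7859 for T against N and 16389 for L against N. H2Bub IFN_TL against IFN_L gained 11128. LPS-gained H3K4me3 regions in IFN_TL and not TL numbered 510.

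With equal list lengths, H3K4me3 gained 3923 in TL against T and 3974 in IFN_T against T and lost 3987 in IFN_L against L, H2Bub lost 23473 in L against N, H3K27ac lost 18590 in T against N, and H4ac lost 6117 in L against N and gained 3216 and lost 3532 in TL against T. In file order, an alternative added after seeing the data, p65 gained 22138 and IRF1 3429, as many as were lost. With peaks within 1 kb merged, H2Bub gained 15982 in T against N, 13436 in L against N and 12021 in IFN_TL against IFN_T. With the centre of the p65 peak inside the IRF1 peak, the overlap was 6.18%.

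In the H3K4me3 model, the bins called for TNF, IFNA and LPS were 2476, 823 and 0 with a TNF by IFNA term. Without a trend IFNA gave 165 and LPS 25, without a filter TNF gave 520 and LPS 22, and after quantile normalization LPS gave 0. Leaving out each list in turn gave 244 to 510 for TNF, 0 to 88 for IFNA and 0 for LPS in every case. In the H2Bub model, TNF, IFNA and LPS gave 669, 1313 and 2254 without a trend, LPS gave 1072 without a filter and 1599 with the longest 75 percent, and leaving out each list in turn gave 0 throughout.

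Of 14 counts of regions by set of lists, 6 moved with peaks within 1 kb merged, all of them for H2Bub, and 2 with the longest 75 percent, where H3K4me3 regions in exactly the 4 lists with LPS numbered 11 and in exactly those without it 0.

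The difference between gained and lost peaks in the share with p65 or IRF1 was examined in 64 results, all added after seeing the data. Apart from sign changes of differences whose interval as deposited excluded 0, it left that interval in 45 results with the longest 75 percent, 30 in windows of equal length, 26 with 50 percent overlap, 15 with equal list lengths and 13 with merged peaks. With p65, the longest 75 percent gave 21.6 points for H3K4me3 T against N, 27.6 for TL against L and 18.04 for IFN_L against L, and for H3K27ac 20.8 for T against N, -11.8 for TL against T and 15.6 for T against L. Windows of equal length gave 2.65 for H3K4me3 IFN_T against T and 3.14 for IFN_TL against TL, and for H2Bub 0.308 for T against N, 0.576 for L against N, -1.63 for IFN against N, -1.75 for IFN_T against T and -1.38 for IFN_TL against TL. Equal list lengths gave 11.3 for H3K4me3 TL against T, 7.12 for IFN_T against T and 0.555 for H2Bub T against N, and 50 percent overlap gave 1.52 for H2Bub T against N and 2.11 for H3K27ac TL against N. With IRF1, windows of equal length gave 2.83 for H4ac L against N.

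Of 384 values under the alternatives, 35 had the opposite sign to the lists as deposited, and in 0 of them did both intervals exclude 0. The interval as deposited excluded 0 in 4: H2Bub L against N with p65 gave -0.426 points with equal list lengths, H4ac TL against L with p65 gave -0.416 points with 50 percent overlap and -2.38 points with the longest 75 percent, and H2Bub IFN_T against IFN with IRF1 gave -0.00346 points with equal list lengths. The interval of the alternative excluded 0 in 5: with p65, H3K27ac L against N gave -3.16 and H3K4me3 L against N 2.23 points with 50 percent overlap, and H4ac L against N gave 2.19 and H3K4me3 IFN against N 5.62 points with the longest 75 percent, and with IRF1, H2Bub L against N gave -0.300 points with equal list lengths.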

Other observations

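The tests of list headers and of LPS and other stimuli, the splits added beside the treatments, the windows of equal length, and the shares with p65 that they concern were chosen after the result was seen. Of gained IRF1 peaks 53.0% lay outside every H3K4me3 and H3K27ac region, and of those without p65 66.4% did, against 16.6% of gained p65 peaks. Among lost peaks the order was the opposite, with 53.1% for IRF1 and 92.6% for p65. No H3K27ac list with IFNA was analysed here, so IRF1 peaks of IFN_T had none of their own condition, while p65 peaks of T had one. Shared p65 sites overlapped H2Bub less often in the lists with IFNA: 33.0% of them did so in N, 28.4% in L, 29.6% in T and 26.3% in TL, against 13.5% in IFN, 16.2% in IFN_L, 15.0% in IFN_T and 16.4% in IFN_TL. The mean over the 4 pairs was -14.1 points (SD 4.14, lower in 4 of 4 pairs, exact sign-flip p = 0.125, the smallest these pairs can give, adjusted p = 0.417 over 60 comparisons). The 4 lists with IFNA come from 1 sample each and the others from 2, so sample number cannot be separated from IFNA.

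H4ac at p65 sites was lower in both lists with LPS. At shared p65 sites it covered 64.1% in N and 60.9% in T, against 47.8% in L and 42.6% in TL, and the H4ac lists with LPS were also shorter. The order of peaks in the files carried information, although no score was given: the places of shared peaks in the p65 N and T lists had a Spearman rho of 0.637 over 2267 peaks, which are not independent replicates.

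The third pattern weighed is the excess of p65 in peaks gained over peaks lost with TNF. For H3K27ac in T against N, peak length as the cause is argued against by windows of equal length at the peak centres. The difference there was 9.85 points, against 12.9 over whole peaks. Unequal lists are argued against by the 11.01 points found at equal list lengths. In windows of equal length H4ac and H3K4me3 kept 20.7 and 8.04 points, while H2Bub fell from 1.005 to 0.308. The H4ac difference for TL against L shrank at equal list lengths, as given above. The H3K4me3 lists share 1 header type and gave 10.9 points, so a difference in headers is not the cause for that mark. For H3K27ac the part of the rescaling stays open. Its comparisons of lists with the same header changed LPS as well as TNF. LPS gave 0.388 points for H3K27ac (-0.124 to 0.901), and between -3.16 and 1.56 under the alternatives. The values of L against N run against LPS giving the same difference at p65 sites of TNF-treated cells. H3K27ac in TL against T gave -6.90 points, which decides nothing here. The p65 list comes from T, which by itself can favour p65 in peaks of T that TL lacks, and the T and TL lists differ in header type. No p65 list with LPS was analysed, so an excess at p65 sites of LPS-treated cells could not be seen. For H3K4me3 another stimulus stays open: contrasts without a change in TNF gave 9.88 points for IFN_TL against IFN_T, 7.29 for TL against T, 6.05 for IFN_L against L, 5.94 for IFN_TL against TL and 4.69 for IFN_T against T, but -0.0225 for L against N and -0.143 for IFN against N. Gained p65 sites overlapped H3K27ac at 67.3% in N and 68.9% in T, and H3K4me3 at 17.6% and 18.2%, and no biological explanation of the excess was tested.

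The model counts were set against other splits of the 8 lists into 4 and 4, with the other treatments kept as terms. For H3K4me3 and TNF, 1 of 33 splits, the real one, gave as many as 794 bins and the highest other gave 0. This count does not decide on chance for TNF, because the other splits leave the TNF effect to the residuals, which lowers their counts. With each split added beside all 3 treatments, TNF gave more bins than the split in 26 of 32 fits and both gave 0 in 6. The highest count of a split there was 894, in a fit that gave 2476 for TNF. For IFNA 2 of 33 splits gave at least 105, the highest other being 336, and for LPS 3 of 33 gave at least 13, the highest other being 2526, so chance cannot be excluded for either. The split with 336 bins sets N, TL, IFN and IFN_TL against the rest, which is the product of TNF and LPS. The split with 2526 bins sets N, L, IFN_T and IFN_TL against the rest, which is the product of TNF and IFNA, and it is also the split with 894. These counts are several times the real ones for IFNA and LPS. Whether they come from interactions of the treatments or from other differences between lists was not tested. For H2Bub the real counts were 0, which 33 of 33 splits reach whatever the data, so the splits decide nothing there. The highest other count was 5144 beside TNF, for the product of IFNA and LPS, 14992 beside IFNA, for the product of TNF and LPS, and 0 beside LPS. The origin of the counts of 5144 and 14992 was not tested either.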
